A study of Homo sapiens with 24 samples.

How the data were processed

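RNA was sequenced from human prostate cancer cell lines and from tumours grown from such lines in nude mice, after treatment with BsAb, a bispecific antibody against integrin α5β1 and αv integrins, or control treatment. The 24 libraries formed 6 experiments of 4 libraries, each with 2 control and 2 BsAb samples, and groups were taken from the cell line, tissue and treatment labels. Cells received 10 µg/mL of antibody for 48 h and xenografts 10 mg/kg weekly. No label said that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Libraries were stranded poly(A) mRNA, per the labels' protocols, and reads were processed on genome build GRCh38, per the submitters' notes. The aligner, the counting program and its annotation are not given in the sources, nor is any step that removed mouse reads from the xenograft tables.

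The authors deposited one table per experiment, in 3 units. The table of DU-145 cells held raw counts per gene symbol. The tables of DU-145 PTEN-mt cells and C4-2B cells held estimated counts per transcript as deposited, which were summed per gene, and the table labelled DU-145 xenograft held estimated counts per gene. The deposited tables of PC-3 cells and of the PC-3 xenograft held a signal: gene counts that the authors had divided by one size factor per library, since every value was a whole multiple of one step (100% of values, within 0.001 of a whole read). The design written before the data were examined assumed raw counts in all 6 tables. For these tables the test was therefore changed to limma on log2(value + 1), and edgeR on the recovered whole reads was added as an alternative.

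In the tables keyed by symbol, copies of a gene at other loci carried a number after the symbol. Such copies marked 3431 genes in the table of DU-145 cells and 181 in that of PC-3 cells. Genes marked in either table were left out of both, so PTEN could not be read in DU-145 cells. The numbered copies alone held at most 0.258% of the counts of a library in DU-145 cells and 0.088% in PC-3 cells. The share held by all genes left out was not counted. In the tables keyed by Ensembl identifier, 57773 genes were read, of which 51996 had a symbol. Genes without a symbol held at most 1.35% of the counts of a library. Coordinates came from a GENCODE annotation of GRCh38.

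Estimated counts were rounded to whole numbers. Counts were tested with the quasi-likelihood test of edgeR 4.0.16 after TMM scaling and filterByExpr. The 2 PC-3 tables were tested with the trend method of limma 3.58.1 with a pseudocount of 1, on genes with a value of at least 10 in at least 2 libraries, and fold changes there are on the log2(value + 1) scale, which understates the change of low genes. Levels are CPM after TMM scaling in the count tables and deposited normalized counts in the PC-3 tables. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Differences of treatment effect between experiments were tested over 16 libraries with edgeR where the tables compared held counts, and over all 24 libraries with limma where a PC-3 table took part. Each difference is named as the first experiment minus the second, each being BsAb minus control on the log2 scale.

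Before the data were examined, 36 lists holding 623 genes were fixed. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of an experiment. The estimated correlation and fry were run beside it. No list of the 6 experiments was called with the estimated correlation. Its smallest adjusted p ran from 0.0577 in DU-145 cells to 0.486 in the libraries labelled DU-145 xenograft. Named genes followed a rule also fixed then: per experiment the 6 largest called rises and 6 largest called falls with a mean CPM of at least 5 and no overlap between the arms, up to 4 members with the smallest p from at most 7 lists, and in every table ITGA5, ITGAV, ITGB1, ITGB3, ITGB5, ITGB6, ITGB8 and FN1, with PTEN, AR and KLK3 in the tables of their experiments. The 5 largest differences in each direction and 8 genes shared by most experiments were named as well. Genes named outside this rule are members of fixed lists, or are said to have been chosen after their values were seen.

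The steps were tested on simulated data with 200 genes changed by known folds, too few to test scaling where most change. At a 2-fold change the test recovered 185 of 195 genes in DU-145 cells, 186 of 198 in PC-3 cells, 175 of 195 in DU-145 PTEN-mt cells, 166 of 183 in C4-2B cells, 125 of 195 in the design of the libraries labelled DU-145 xenograft and 138 of 192 in that of the PC-3 xenograft. At a 1.5-fold change it recovered 0 of 192 and 4 of 187 in the last 2. False calls at 2-fold numbered 4, 14, 27, 23, 19 and 12 in that order. For differences at a 2-fold change, 152 of 200 were recovered with 3 false calls for DU-145 PTEN-mt cells minus DU-145 cells and 142 with 6 for PC-3 cells minus DU-145 cells. The other differences brought more false calls: 36 beside 37 recovered for C4-2B cells minus the mean of DU-145 and PC-3 cells, 78 beside 153 for the libraries labelled DU-145 xenograft minus DU-145 cells, and 61 beside 135 for PC-3 xenograft minus PC-3 cells.

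Alternatives were library size alone and DESeq2 size factors as scaling, no filter, a stricter filter, DESeq2 1.42.0, the spread shared over the 12 groups, a replicate block, at least 2-fold changes and each library left out in turn. Chosen after seeing the data were edgeR on recovered reads, TMM on the deposited values, other pseudocounts, genes with copies kept, a crossed block, and a restriction of PC-3 cells to genes read in the PC-3 xenograft. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.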

Results

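Gene expression was measured by RNA sequencing in 24 libraries of human prostate cancer cells after BsAb or control treatment. Integrins are cell surface receptors for matrix proteins such as fibronectin. The lines were DU-145 and PC-3, which lack androgen dependence, a DU-145 line labelled PTEN-mt, and C4-2B, an androgen receptor positive line derived from LNCaP. DU-145 and PC-3 were also labelled as xenografts in nude mice. Each of the 6 experiments held 2 control and 2 BsAb libraries, so n = 2 for every mean ± SD. Depth was 28.5 to 35.8 M counts per library in DU-145 cells, 13.5 to 17.4 in PC-3 cells, 22.9 to 26.0 in DU-145 PTEN-mt cells, and 21.5 to 24.3 in C4-2B cells. It was 14.6 to 38.3 in the libraries labelled DU-145 xenograft and 16.3 to 17.5 in the PC-3 xenograft. The SD of the log2 difference between replicates was 0.394 for the controls labelled DU-145 xenograft and 0.363 for those of the PC-3 xenograft, against 0.105 for the controls of DU-145 cells.

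The antibody's targets are encoded on several chromosomes of GRCh38. ITGA5 lies on chromosome 12 from 54395261 to 54419460 on the minus strand, and its partner ITGB1 on chromosome 10 from 32900319 to 33005792 on the minus strand. ITGAV lies on chromosome 2 from 186590065 to 186680901 on the plus strand. The genes of the other αv partners are ITGB3 (chromosome 17, 47253846 to 47311816), ITGB5 (chromosome 3, 124761948 to 124901418), ITGB6 (chromosome 2, 160099666 to 160200313) and ITGB8 (chromosome 7, 20330702 to 20415754). FN1, which encodes the ligand fibronectin, lies on chromosome 2 from 215360440 to 215436172 on the minus strand. Values are whole-gene counts, as the tables do not part exons from untranslated regions.

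In DU-145 cells, genes read out by the YAP/TAZ coactivators fell with BsAb while interferon-stimulated genes rose. CCN1, a matricellular protein gene and YAP target, fell from 786 ± 16.5 to 65.2 ± 1.32 CPM, a log2 fold change of −3.59 (SE 0.04, adjusted p = 1.52e-25), and CCN2 fell from 78.8 ± 2.99 to 9.49 ± 0.704 CPM. DKK1, which encodes a secreted Wnt inhibitor, fell from 148 ± 2.19 to 11.1 ± 0.26 CPM (log2 −3.73, SE 0.06, adjusted p = 6.94e-23), and the AP-1 subunit gene FOSL1 fell from 259 ± 4.45 to 28.3 ± 1 CPM. The neurotrophin gene BDNF (log2 −3.23) and DAW1 (log2 −2.90) completed the 6 largest called falls at a mean of at least 5 CPM without overlap between the arms. Within the same limits, the largest rises were in OAS2, from 2.69 ± 0.262 to 25.5 ± 1.8 CPM (log2 3.24, SE 0.12, adjusted p = 1.46e-16), XAF1 (3.23) and OAS1 (3.04), all interferon-stimulated genes. They were followed by BMF, which encodes a pro-apoptotic BH3-only protein and rose from 20.5 ± 1.15 to 127 ± 1.95 CPM, the water and glycerol channel gene AQP3 (log2 2.60) and AKR1C2 (log2 2.53), whose reads are hard to part from those of its close paralogs.

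Of 20 YAP/TAZ targets tested in DU-145 cells, 19 fell over all genes and 20 adjusted over the list alone, with a median log2 fold change of −1.29 (camera adjusted p = 1.13e-38, adjusted p = 0.0577 with an estimated correlation). AMOTL2 fell by 2.32 and GADD45B by 2.76 on the log2 scale. All 22 interferon-stimulated genes tested rose, also when adjusted over the list alone, with a median of 1.87 (camera adjusted p = 8.19e-37, adjusted p = 0.0577 with an estimated correlation). Among them were MX1, from 34.5 ± 0.208 to 167 ± 1.21 CPM, IFIT1 (2.18), OASL (2.02) and IFIT3 (1.76). Replication and mitosis genes fell as well. All 22 S-phase genes fell over all genes and adjusted over the list alone (median −1.03, camera adjusted p = 6.46e-35, adjusted p = 0.0577 with an estimated correlation). They were led by the ribonucleotide reductase gene RRM2, from 548 ± 13.5 to 169 ± 0.958 CPM, and included CDC6 (−1.63), MCM10 (−1.69) and UHRF1 (−1.27). All 24 G2/M genes fell in the same counts (median −0.96, camera adjusted p = 4.14e-27, adjusted p = 0.0691 with an estimated correlation), with CDC20 at −1.47, AURKB at −1.66, CDK1 at −1.05 and TPX2 at −1.02.

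Genes downstream of growth factor and cytoskeletal signals followed. Of 19 ERK output genes, 17 fell and 2 rose, adjusted over the list alone as over all genes (median −1.05, camera adjusted p = 1.1e-17, adjusted p = 0.0691 with an estimated correlation). The receptor kinase gene EPHA2 fell from 202 to 33.6 CPM, the cyclin D1 gene CCND1 from 717 to 229 CPM and PHLDA1 from 343 to 103 CPM. Of 15 actin and SRF targets, 12 fell and 1 rose in both counts, the list adjusted over the list alone included (median −0.89, camera adjusted p = 2.39e-10, adjusted p = 0.105 with an estimated correlation). FHL2 fell from 340 to 100.1 CPM, ACTB from 4616 to 1868 CPM, TPM4 by 1.23 and CNN2 by 1.16 on the log2 scale. Of 10 heat-shock genes, 8 fell and 1 rose, again also adjusted over the list alone (median −0.66, camera adjusted p = 5.63e-07, adjusted p = 0.125 with an estimated correlation). The chaperone genes HSP90AA1 had −1.26, HSPA8 −1.22, HSPD1 −1.21 and HSPH1 −0.75.

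Among the antibody's targets in DU-145 cells, ITGB3 fell from 13.9 ± 0.598 to 7.58 ± 0.995 CPM (log2 −0.87, SE 0.11, adjusted p = 3.29e-07) and ITGB5 from 86.6 ± 4.73 to 64 ± 0.512 CPM (log2 −0.44). FN1 rose from 27 ± 2.04 to 37.6 ± 0.676 CPM (log2 0.48, adjusted p = 1.28e-06). ITGB1 fell from 2665 to 2242 CPM (log2 −0.25, adjusted p = 2.8e-07), a call that ended with scaling by library size alone (−0.04). ITGA5 stood at 86.7 ± 2.89 and 89.6 ± 2.62 CPM (log2 0.05, SE 0.05, adjusted p = 0.388), and was called with library size alone (0.254 for ITGA5 in DU-145 cells). ITGAV had a log2 fold change of 0.11 (adjusted p = 0.00773), uncalled for ITGAV in DU-145 cells without control 1 (0.108), control 2 (0.091) or BsAb 1 (0.083). ITGB6, at 0.796 and 1.44 CPM, had 0.86 (adjusted p = 0.027), uncalled for ITGB6 in DU-145 cells without control 2 (0.601) or BsAb 1 (0.682), and ITGB8 had 0.48 (adjusted p = 0.0527), called for ITGB8 in DU-145 cells without control 1 (0.708) or BsAb 1 (0.604).

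Over the 15119 genes tested in DU-145 cells, 4493 were higher and 4897 lower with BsAb, of which 1146 and 678 by at least 2-fold, and 40 of the 43 called genes named kept their calls in all alternatives. Scaling by library size alone, which moved the median of all genes by 0.207, gave 7035 higher and 3080 lower, and genes under 2 CPM had a median of 0.404.

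In PC-3 cells, the largest falls with BsAb exceeded the largest rises. ID4, a helix-loop-helix inhibitor gene, fell from 176 ± 7.5 to 9.77 ± 2.49 normalized counts (log2 −4.06, SE 0.26, adjusted p = 6.19e-10) and the smooth muscle actin gene ACTA2 from 501 ± 13.4 to 49.5 ± 6.06 (log2 −3.32, SE 0.14, adjusted p = 7.5e-13). LBH fell by 3.60, ALPK2 by 3.49, the neuregulin gene NRG1 by 3.33 and the YAP target ANKRD1 by 3.30 on the log2 scale. Rises were smaller. HPGD, which encodes the enzyme that inactivates prostaglandins, rose from 801 ± 12.9 to 1221 ± 46.1 normalized counts (log2 0.61, SE 0.06, adjusted p = 6.7e-07). RN7SK rose from 54.6 ± 29.8 to 122 ± 2.19 (log2 1.26, adjusted p = 0.00484), uncalled for RN7SK in PC-3 cells without control 2 (0.68).

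Several of these genes hardly had reads in PC-3 xenografts. Levels were 0.0149 CPM for ID4, 0.0154 for LBH, 0.0308 for ALPK2, 0.0446 for NRG1, 0.877 for ACTA2 and 0.147 for ANKRD1. Genes absent or nearly absent from PC-3 xenografts, chosen after the values were seen, went both ways. The glial filament gene GFAP stood at 24.3 and 21.8 CPM in the control libraries of PC-3 cells and 2.52 and 2.52 CPM with BsAb. The adhesion gene CTNNA1 stood at 34.5 and 25.5 CPM against 15.4 and 10.3 CPM, with 0.23 to 0.369 CPM in PC-3 xenografts. KLK3, at 0 CPM in PC-3 xenografts, stood at 6.82 and 6.46 CPM in the controls and 10.1 and 8.09 CPM with BsAb.

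Of 17 actin and SRF targets in PC-3 cells, 8 fell over all genes and 11 adjusted over the list alone (median −0.22, camera adjusted p = 3.07e-14, adjusted p = 0.363 with an estimated correlation). They included ACTA2, TAGLN (−3.04, 1.88 CPM in PC-3 xenografts), CNN3 (−1.25, 12.6 CPM in PC-3 xenografts) and TPM1 (−0.60, 42 CPM in PC-3 xenografts). Of 20 YAP/TAZ targets, 5 fell over all genes, and 10 fell and 1 rose adjusted over the list alone (median −0.19, camera adjusted p = 2.45e-06, adjusted p = 0.363 with an estimated correlation). CCN2 fell from 680 ± 12.2 to 382 ± 3.66 normalized counts (log2 −0.83) and CCN1 by 0.74 on the log2 scale, with 19.8 and 30.7 CPM in PC-3 xenografts. Of 16 NF-kB and inflammatory genes, 3 fell in both counts, the one adjusted over the list alone included (median −0.12, camera adjusted p = 0.00243, adjusted p = 0.363 with an estimated correlation). The chemokine gene CCL2 fell from 205 to 30.7 normalized counts and had 0 CPM in PC-3 xenografts, NFKBIA fell by 0.41 on the log2 scale, and TNFAIP3 (−0.94) was uncalled for TNFAIP3 in PC-3 cells without control 1 (−0.757).

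Hypoxia and glycolysis genes rose in PC-3 cells, 11 of 21 over all genes and 17 adjusted over the list alone (median 0.17, camera adjusted p = 2.8e-14, adjusted p = 0.363 with an estimated correlation). NDRG1 had a log2 fold change of 0.29 (SE 0.04), ADM 0.31, the mitophagy receptor gene BNIP3 0.23 and the carbonic anhydrase gene CA9 0.23. Of 22 S-phase genes, 6 fell over all genes and 10 adjusted over the list alone (median −0.13, camera adjusted p = 7.45e-08, adjusted p = 0.363 with an estimated correlation), UHRF1 by 0.25. Of 13 mitochondrially encoded genes, 1 rose over all genes and 8 adjusted over the list alone (median 0.22, camera adjusted p = 2.45e-06, adjusted p = 0.466 with an estimated correlation). The call ended for the list of mitochondrially encoded genes in PC-3 cells without control 1 (0.064) or BsAb 1 (0.006), and mitochondrial genes held 1.87% and 2.42% of the control counts and 2.88% and 2.24% with BsAb. Interferon-stimulated genes had a median of 0.16 and no called member among 20 by limma (camera adjusted p = 0.0538).

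ITGA5 rose in PC-3 cells from 5217 ± 28.6 to 6114 ± 39.2 normalized counts (log2 0.23, SE 0.04, adjusted p = 0.00152) and ITGB5 fell from 1329 ± 37.6 to 1098 ± 58.4 (log2 −0.28, adjusted p = 0.00661). ITGAV had −0.11 (adjusted p = 0.334), ITGB1 0.04 (0.739), ITGB3 −0.08 (0.922), ITGB6 −0.26 (0.771), ITGB8 0.10 (0.544) and FN1 0.13 (0.201). Over the 13302 genes tested with limma, 238 were higher and 334 lower, of which 2 and 180 by at least 2-fold. Among genes with at least 1 CPM in PC-3 xenografts, a restriction chosen after seeing the data, 221 were higher and 168 lower, and scaling by library size alone gave 107 and 487. The counts were 199 and 158 without control 1, 194 and 183 without control 2, 174 and 338 without BsAb 1, and 221 and 338 without BsAb 2. With the spread shared over the 12 groups they were 7 and 112. ID4, LBH, ALPK2, NRG1, ACTA2, ANKRD1, TAGLN, TPM1, CCN2, CCL2 and TNFAIP3 were called there, and HPGD, ITGA5, ITGB5, CCN1, CNN3, NFKBIA and the 4 named hypoxia genes were not.

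In DU-145 PTEN-mt cells, interferon-stimulated genes rose and YAP/TAZ targets fell with BsAb as groups, and single genes changed by more. The calprotectin gene S100A9 rose from 12.9 ± 1.61 to 146 ± 12.6 CPM (log2 3.50, SE 0.08, adjusted p = 4.06e-11) and its partner S100A8 by 3.70 on the log2 scale. GPX2, an epithelial glutathione peroxidase gene, rose from 0.501 to 10.7 CPM (log2 4.42, SE 0.24, adjusted p = 2.21e-08), DMBT1 from 5.82 to 73.9 CPM, and the paralogs AKR1C1 (3.37) and AKR1C2 (3.22), whose reads are hard to part, rose as well. ANKRD1 fell from 231 ± 11.9 to 58.4 ± 3.39 CPM (log2 −1.98, adjusted p = 7.48e-11), TAGLN from 58.9 to 14.1 CPM, the cytokine gene IL11 from 13.4 to 2.7 CPM, PEAR1 by 2.06 and MARCHF4 by 1.75. RPS17, which has near-identical copies and whose BsAb libraries differed (19.6 ± 14.4 CPM), is uncertain at −3.45.

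Of 23 interferon-stimulated genes in DU-145 PTEN-mt cells, 22 rose over all genes and 22 adjusted over the list alone (median 1.72, camera adjusted p = 6.75e-39, adjusted p = 0.187 with an estimated correlation). Among them were OASL (2.33), IFI6 from 14.1 to 65.3 CPM, IFIT3 (1.76) and ISG15 (1.73). Of 21 YAP/TAZ targets, 15 fell and 2 rose, adjusted over the list alone as over all genes (median −0.41, camera adjusted p = 3.06e-14, adjusted p = 0.187 with an estimated correlation). CCN2 fell from 99.4 to 36.3 CPM and CCN1 from 480 to 219 CPM, while IGFBP3, which binds insulin-like growth factors, rose from 63.4 to 235 CPM. G2/M genes fell, 21 of 24 over all genes and 22 adjusted over the list alone (median −0.37, camera adjusted p = 2.44e-13, adjusted p = 0.22 with an estimated correlation), with CDC20 at −0.64, CENPE at −0.65, BUB1 at −0.47 and AURKA at −0.42. S-phase genes fell, 16 of 21 in both counts, the one adjusted over the list alone included (median −0.27, camera adjusted p = 5.17e-07, adjusted p = 0.247 with an estimated correlation), with MCM10 at −0.65 and MCM4 at −0.47.

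Hypoxia and glycolysis genes rose in DU-145 PTEN-mt cells, 17 of 22 with 2 lower, adjusted over the list alone as over all genes (median 0.40, camera adjusted p = 6.39e-11, adjusted p = 0.187 with an estimated correlation). NDRG1 rose from 104 to 199 CPM, VEGFA, the vascular endothelial growth factor gene, from 204 to 364 CPM, PGK1 by 0.54 on the log2 scale, and ALDOA from 2190 to 3142 CPM. Lysosome and autophagy genes rose, 17 of 25 in both counts, also adjusted over the list alone (median 0.31, camera adjusted p = 2.93e-09, adjusted p = 0.187 with an estimated correlation), with the protease genes CTSD (1.06), CTSB (0.85) and CTSA (0.83), and GRN (0.63). Of 13 replication-dependent histone genes, 8 rose in both counts, also adjusted over the list alone (median 0.84, camera adjusted p = 1e-05, adjusted p = 0.187 with an estimated correlation), with H2BC21 at 0.99, H1-2 at 0.95, H2AC6 at 0.74 and H2BC12 at 0.61. As this list was fixed as a check of poly(A) selection and RNA quality, the shift need not be one of expression.

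ITGA5 rose in DU-145 PTEN-mt cells from 152 ± 0.0136 to 238 ± 0.349 CPM (log2 0.65, SE 0.04, adjusted p = 5.1e-08), and ITGB3 from 14.8 to 21.8 CPM (log2 0.56, adjusted p = 0.000218). FN1 rose from 9.49 to 14.3 CPM (log2 0.58, adjusted p = 0.00325). PTEN, the lipid phosphatase gene on chromosome 10 from 87863113 to 87971930, rose from 60 ± 1.21 to 74.7 ± 2.46 CPM (log2 0.32, SE 0.05, adjusted p = 0.0004). ITGAV had −0.17 (adjusted p = 0.00772), uncalled for ITGAV in DU-145 PTEN-mt cells without BsAb 1 (−0.165). ITGB8, at 0.0808 and 0.665 CPM, was called (adjusted p = 0.00465), but not for ITGB8 in DU-145 PTEN-mt cells without control 2 (2.39) or BsAb 2 (2.52). ITGB1 had 0.06 (0.234) and ITGB5 −0.05 (0.375). Over the 15092 genes tested with edgeR, 3181 were higher and 3109 lower, of which 543 and 183 by at least 2-fold. With the spread shared over the 12 groups these were 1706 and 1863, and ITGA5, FN1 and NDRG1 were uncalled.

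In C4-2B cells, mitochondrially encoded transcripts fell and hypoxia and glycolysis genes rose with BsAb. Among called genes of at least 5 CPM without overlap between the arms, the stress cytokine gene GDF15 rose most, from 131 ± 4.94 to 295 ± 4.4 CPM (log2 1.17, SE 0.04, adjusted p = 2.05e-09). The circadian repressor gene BHLHE40, from 24.6 to 51.6 CPM, and CRISP3 (0.99) came next. REPS2 (0.93), the mTORC1 inhibitor gene DDIT4 (0.91) and NEDD9 (0.91) followed. IGFBP3 fell from 121 ± 3.48 to 31.7 ± 0.423 CPM (log2 −1.93, SE 0.05, adjusted p = 2.13e-10), the chaperone gene CLU from 166 to 70.3 CPM, the BMP-responsive gene ID1 from 107 to 45.1 CPM, KRT80 from 12.5 to 5.32 CPM and SPSB1 from 7.34 to 3.21 CPM. IGHM (−1.29, adjusted p = 0.0165) was uncalled for IGHM in C4-2B cells without control 1 (−1.063) or BsAb 1 (−0.737).

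All 13 mitochondrially encoded genes fell in C4-2B cells, also when adjusted over the list alone (median −0.55, camera adjusted p = 1.72e-89, adjusted p = 0.134 with an estimated correlation). MT-ND3 fell from 399 to 235 CPM, MT-ND2 from 1611 to 1061 CPM, MT-ND1 by 0.59 and MT-ATP8 by 0.52 on the log2 scale. These genes held 3.77% and 3.65% of counts in the controls and 2.62% and 2.49% with BsAb. Of 23 hypoxia and glycolysis genes, 16 rose and 1 fell over all genes, and 18 rose and 1 fell adjusted over the list alone (median 0.37, camera adjusted p = 3.95e-21, adjusted p = 0.134 with an estimated correlation). The glycolytic regulator gene PFKFB3 had 0.59, HK2 0.48, the glucose transporter gene SLC2A1 0.37 and PGK1 0.30. Of 15 actin and SRF targets, 6 fell over all genes and 8 adjusted over the list alone (median −0.26, camera adjusted p = 2.31e-10, adjusted p = 0.134 with an estimated correlation), MYL9 from 6.11 to 1.01 CPM, TPM4 from 245 to 178 CPM and CNN2 by 0.58. Of 13 replication-dependent histone genes, 8 fell over all genes and 10 adjusted over the list alone (median −0.29, camera adjusted p = 9.38e-08, adjusted p = 0.134 with an estimated correlation), H1-2 by 0.29 and H2BC21 by 0.33.

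FOXO targets passed camera upward in C4-2B cells, with 4 of 15 higher over all genes and 6 adjusted over the list alone (median 0.14, camera adjusted p = 1.29e-07, adjusted p = 0.134 with an estimated correlation). SESN3 rose from 51.7 to 93.2 CPM, and TXNIP, which restrains glucose uptake, from 68.1 to 102 CPM. Of 10 fatty acid synthesis genes, 6 rose over all genes, and 6 rose and 1 fell adjusted over the list alone (median 0.20, camera adjusted p = 1.29e-07, adjusted p = 0.134 with an estimated correlation). The desaturase gene SCD rose from 489 to 633 CPM, ELOVL6 by 0.53, ACLY by 0.24 and FASN by 0.21 on the log2 scale. Of 20 TGF-beta targets, 8 fell and 2 rose over all genes, and 10 fell and 2 rose adjusted over the list alone (median −0.10, camera adjusted p = 9.95e-06, adjusted p = 0.134 with an estimated correlation), with ID1, ID2 (−0.90) and ID3 (−0.65) lower and BHLHE40 higher.

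AR stood at 184 ± 4.61 and 189 ± 3.26 CPM in C4-2B cells (log2 0.04, adjusted p = 0.553) and the prostate-specific antigen gene KLK3 at 2167 and 2144 CPM (log2 −0.02, adjusted p = 0.742). ITGA5 had 0.05 (0.737), ITGAV 0.02 (0.819), ITGB1 0.08 (0.116), ITGB6 −0.25 (0.745) and ITGB8 −0.40 (0.465). FN1 had −0.08 (0.139) and was called for FN1 in C4-2B cells without control 1 (−0.119), and ITGB5 had −0.23 (adjusted p = 0.0135) and was uncalled for ITGB5 in C4-2B cells without BsAb 1 (−0.2) or BsAb 2 (−0.3). Over the 15111 genes tested with edgeR, 1038 were higher and 916 lower, of which 32 and 49 by at least 2-fold. The counts were 716 and 567 without control 1, 1411 and 1188 without control 2, 270 and 259 without BsAb 1, and 279 and 296 without BsAb 2, and library size alone gave 1224 and 716. With the spread shared over the 12 groups 16 and 31 were called. IGFBP3, CLU, ID1, ID2, KRT80, SPSB1, MT-ND3, TPM4, MYL9, CNN2 and TXNIP were among them, the other called genes named for C4-2B were not, and the TGF-beta list was uncalled.

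The libraries labelled DU-145 xenograft carried the expression of PC-3. CTNNA1, at 593 to 647 CPM in DU-145 cells, stood at 1.11 to 2.87 CPM in them and at 0.23 to 0.369 CPM in PC-3 xenografts, and STAT3, at 375 to 544 CPM in DU-145 cells, stood at 0.775 to 3 CPM. The 55 genes of PC-3, at 50 CPM or more there and at most 1 CPM in DU-145 cells, had medians of 56.9 to 80.7 CPM. The 14 genes of DU-145, chosen the other way round, had medians of 0.17 to 0.478 CPM, against 0.287 to 0.522 CPM in PC-3 cells. These genes were chosen after the values were seen, and directions below hold for libraries so labelled.

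**Figure D1:**
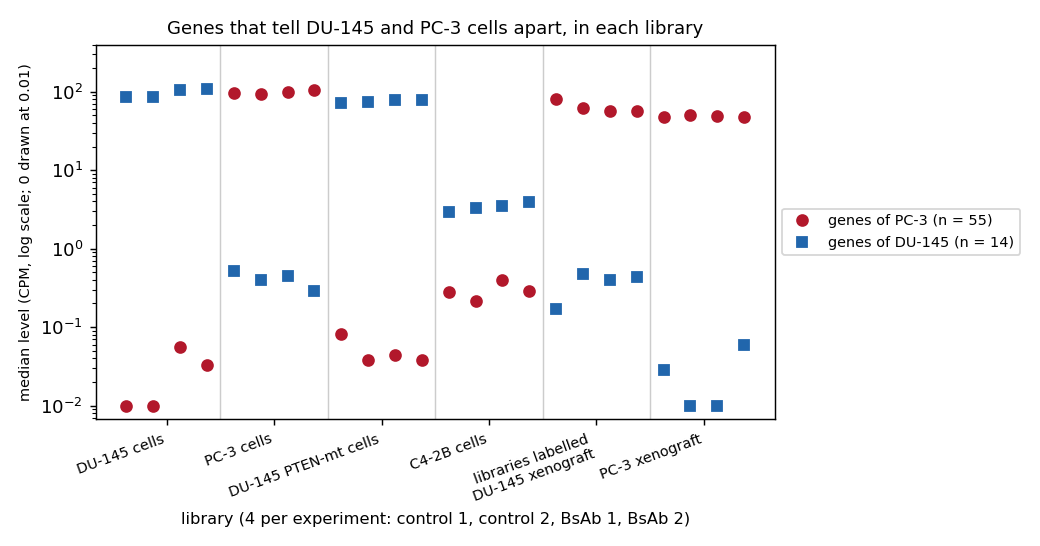
Median CPM on a log scale, with 0 drawn at 0.01, of 55 genes of PC-3 and 14 genes of DU-145, for each of 24 libraries. These genes have at least 50 CPM in that line and at most 1 CPM in the other. The 4 libraries labelled DU-145 xenograft lie at 56.9 to 80.7 CPM for the genes of PC-3 and at 0.17 to 0.478 CPM for the genes of DU-145.

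In the libraries labelled DU-145 xenograft, interferon-stimulated genes were higher and mitosis genes lower with BsAb as groups, and no single gene was called. IRF9, a subunit of the interferon-activated factor ISGF3, stood at 15.1 ± 4.02 CPM in controls and 56.3 ± 5.29 CPM with BsAb (log2 1.91, SE 0.20, adjusted p = 0.236). IFI44L stood at 4.46 and 43 CPM, BST2 at 3.31 and 18.6 CPM and STAT1 at 97.5 and 161 CPM. Of 24 interferon-stimulated genes, 14 were higher adjusted over the list alone and 0 over all genes (median 1.18, camera adjusted p = 3e-27, adjusted p = 0.486 with an estimated correlation). Of 24 G2/M genes, 22 were lower adjusted over the list alone and 0 over all genes (median −0.63, camera adjusted p = 4.1e-27, adjusted p = 0.486 with an estimated correlation), with UBE2C at 67.6 and 38.9 CPM, PLK1 at 69.3 and 38 CPM and CDK1 at 120 and 82.5 CPM. Of 21 S-phase genes, 8 were lower adjusted over the list alone (median −0.33, camera adjusted p = 4.8e-09, adjusted p = 0.486 with an estimated correlation), with RRM2 at −0.73 and TYMS at −0.60. Each of these genes kept its sign when control 1 or control 2 was left out. Calls made in such fits take their spread from the BsAb pair alone, which differed less than the controls, and say little.

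Matrix and adhesion genes passed camera downward as groups in the libraries labelled DU-145 xenograft, again with no single gene called over all genes. Of 28 genes of extracellular matrix and integrin ligands, 6 were lower adjusted over the list alone (median −0.37, camera adjusted p = 2.62e-05, adjusted p = 0.486 with an estimated correlation), with the collagen gene COL5A2 at 156 and 79.5 CPM, the laminin gene LAMC2 at 49.5 and 26.4 CPM, and COL6A2 at 184 and 114 CPM. Of 22 focal adhesion components, 2 were lower adjusted over the list alone (median −0.23, camera adjusted p = 0.000234, adjusted p = 0.486 with an estimated correlation), with the paxillin gene PXN at −0.58, FLNA at −0.54 and ZYX at 0.39. Of 22 hypoxia and glycolysis genes, 0 passed by edgeR adjusted over the list alone (median −0.42, camera adjusted p = 0.00164, adjusted p = 0.608 with an estimated correlation). That list is set by control 1, whose mean log2 level was 8.54 against 7.2 to 7.48 in the other libraries, since the median turned to 0.145 for the list of hypoxia and glycolysis genes in DU-145 xenograft without control 1. ADM stood at 87.1 ± 105 CPM in controls and 14 ± 1.71 CPM with BsAb.

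ITGA5 stood at 79.4 ± 44.9 and 36 ± 2.09 CPM in the libraries labelled DU-145 xenograft (log2 −1.14, SE 0.38, adjusted p = 0.306). It was called for ITGA5 in DU-145 xenograft without control 1 (−0.406) and without control 2 (−1.625). ITGB1 had −0.34 (0.314), ITGAV −0.55 (0.31), ITGB3 0.54 (0.445), ITGB5 −0.29 (0.306), ITGB8 0.56 (0.538) and FN1 −0.52 (0.342). Called without control 2 were ITGAV in DU-145 xenograft libraries (−0.791), ITGB1 in DU-145 xenograft libraries (−0.477) and ITGB8 in DU-145 xenograft libraries (1.27). Called without control 1 were ITGB5 in DU-145 xenograft libraries (−0.353) and FN1 in DU-145 xenograft libraries (−0.732). Over 16309 genes tested with edgeR, 0 were higher and 0 lower, with 2303 under an unadjusted p of 0.05 where chance gives 815, and DESeq2 called 220 higher and 169 lower. The edgeR counts were 557 and 524 without control 1, 1819 and 1971 without control 2 and 1 and 0 without BsAb 1, 751 and 652 with no filter, and 831 and 1056 with the spread shared over the 12 groups.

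In the PC-3 xenograft, interferon-stimulated genes were higher with BsAb as a group, and no single gene was called. IFI6 stood at 136 ± 17 normalized counts in controls and 484 ± 107 with BsAb (log2 1.82, SE 0.20, adjusted p = 0.163), and ISG15 at 803 ± 13.3 and 1513 ± 41.7 (log2 0.91, adjusted p = 0.167). BST2 stood at 42.7 and 132, and IFI27 at 17.5 and 104 normalized counts. Calls of each without control 1 or 2 rest on the spread of the BsAb pair and say little. Of 22 interferon-stimulated genes, 11 were higher adjusted over the list alone and 0 over all genes (median 0.50, camera adjusted p = 3.28e-15, adjusted p = 0.376 with an estimated correlation). Of 21 cholesterol biosynthesis genes, 2 were higher adjusted over the list alone (median 0.30, camera adjusted p = 2.23e-08, adjusted p = 0.957 with an estimated correlation), PCSK9, which lowers LDL receptor levels, at 1.69 and SC5D at 1.02. Of 13 mitochondrially encoded genes, 2 were lower adjusted over the list alone (median −0.37, camera adjusted p = 9.57e-08, adjusted p = 0.957 with an estimated correlation), with MT-ATP8 at −0.84, and they held 5.68% and 5.88% of control counts and 4.95% and 4.34% with BsAb.

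Further lists of the PC-3 xenograft depended on control 2. For 28 genes of extracellular matrix and integrin ligands, 2 were lower adjusted over the list alone (median −0.19, camera adjusted p = 5.38e-05, adjusted p = 0.957 with an estimated correlation), with TNC at −0.72 and COL3A1 at −1.15, and the call ended for the list of extracellular matrix and integrin ligands in PC-3 xenograft without control 2 (0.028). For 19 TGF-beta targets, 1 was lower adjusted over the list alone (median −0.26, camera adjusted p = 0.000222, adjusted p = 0.957 with an estimated correlation), PMEPA1 at 1168 ± 407 and 355 ± 5.28 normalized counts, and the call ended for the list of TGF-beta targets in PC-3 xenograft without control 2 (−0.152). For 21 S-phase genes, 0 passed by limma adjusted over the list alone (median 0.19, camera adjusted p = 0.0114, adjusted p = 0.957 with an estimated correlation). The sign turned for the list of S-phase genes in PC-3 xenograft without control 2 (−0.072), and the call ended without BsAb 2 (0.103).

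ITGA5 stood at 2266 ± 1853 and 1784 ± 548 normalized counts in the PC-3 xenograft (log2 −0.09, SE 0.51, adjusted p = 0.99). It was called lower for ITGA5 in PC-3 xenograft without control 1 (−1.038) and higher without control 2 (0.865). ITGAV had −0.32 (0.906) and was called for ITGAV in PC-3 xenograft without control 1 (−0.748), and ITGB1 had −0.11 (0.954), ITGB3 0.01 (0.996), ITGB5 −0.15 (0.927), ITGB8 0.17 (0.961) and FN1 −0.49 (0.853). Over 15000 genes tested with limma, 0 were higher and 0 lower, with 899 under an unadjusted p of 0.05 where chance gives 750, edgeR on recovered reads called 0 and 0, and DESeq2 called 21 and 16. The limma counts were 82 and 163 without control 1, 198 and 34 without control 2, and 1 and 1 without BsAb 2, and 173 and 144 with the spread shared over the 12 groups.

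**Figure D2:**
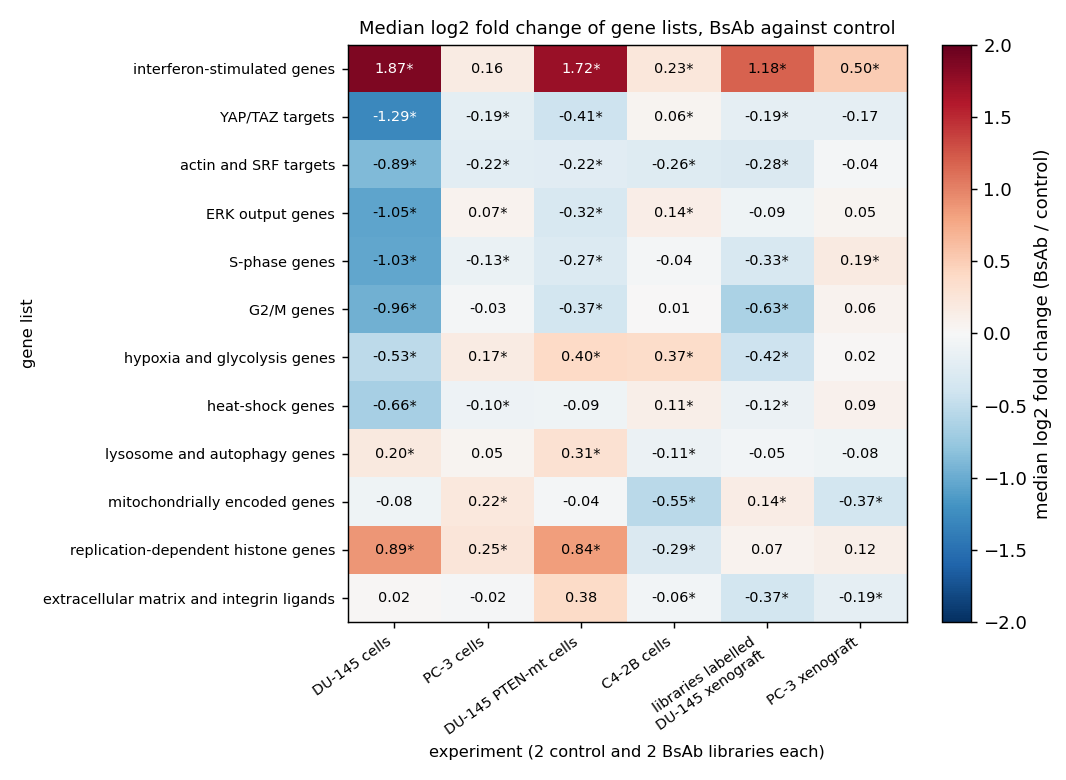
Median log2 fold change, BsAb over control, of the tested members of 12 fixed gene lists in each of the 6 experiments, with the value in each cell, red for higher, blue for lower and an asterisk for a camera adjusted p under 0.05. Interferon-stimulated genes reach 1.87 in DU-145 cells, 1.72 in DU-145 PTEN-mt cells and 0.16 in PC-3 cells, and YAP/TAZ targets −1.29, −0.41 and −0.19.

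Genes that moved the same way in all 4 cell experiments were led by CCN1, with log2 fold changes of −3.59 in DU-145, −0.74 in PC-3, −1.13 in DU-145 PTEN-mt and −0.91 in C4-2B cells. MYL9 had −1.27, −1.19, −0.32 and −2.58 in that order, THBS1 −1.39, −1.87, −0.57 and −0.67, and ENC1 −1.52, −0.95, −0.33 and −0.55. RNA of other cells may add to the PC-3 falls of MYL9 and THBS1, and MYL9 was low in C4-2B. TXNIP had 0.76, 0.26, 2.04 and 0.59, BHLHE40 0.77, 0.17, 0.98 and 1.07, and EGLN3, a HIF prolyl hydroxylase gene, 0.57, 0.19, 1.66 and 0.46. In all, 9 genes were higher and 11 lower in each of the 4. Between DU-145 and DU-145 PTEN-mt cells, 1665 genes were higher in both, against 843 for independent lists, and 2146 lower in both, against 1010 (Fisher's exact p = 3.85e-303 for higher). PC-3 and DU-145 PTEN-mt cells shared 111 higher genes, against 46.9 (Fisher's exact p = 1.29e-22), and 86 lower ones, against 59.9 (Fisher's exact p = 0.000183). DU-145 and PC-3 cells shared 75 higher genes, against 63.2 (Fisher's exact p = 0.0832), and 112 lower ones, against 95.7 (Fisher's exact p = 0.0357), with 187 called in opposite directions, against 156. DU-145 and C4-2B cells shared 277 higher genes, against 278 (Fisher's exact p = 1), and 322 lower ones, against 279 (Fisher's exact p = 0.000808), with 620 opposite, against 575. PC-3 and C4-2B cells shared 33 higher genes, against 17.4 (Fisher's exact p = 0.000325), and 22 lower ones, against 15.4 (Fisher's exact p = 0.0837), with 56 opposite, against 33.4. DU-145 PTEN-mt and C4-2B cells shared 271 higher genes, against 214 (Fisher's exact p = 6.78e-06), and 204 lower ones, against 188 (Fisher's exact p = 0.186), with 511 opposite, against 403. These experiments shared no control libraries.

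**Figure D3:**
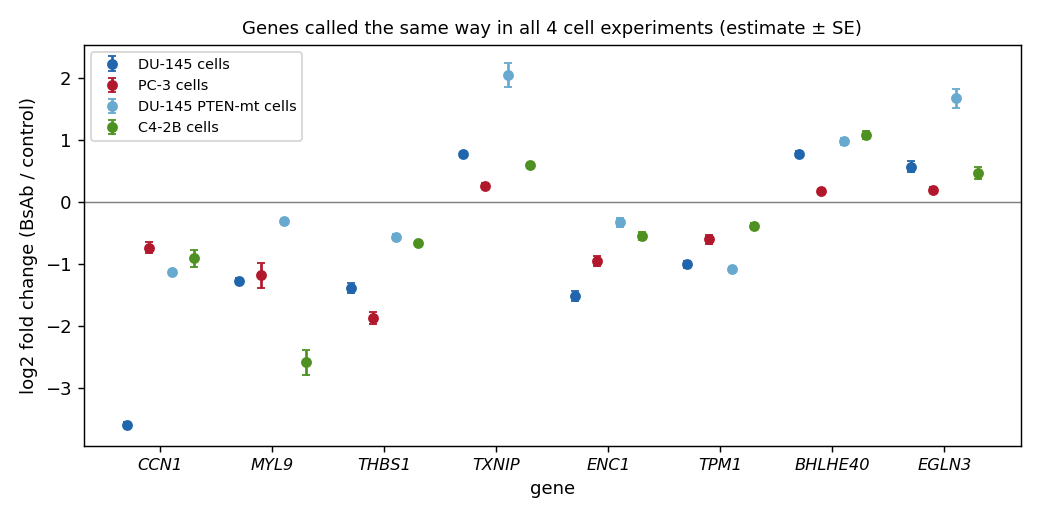
Log2 fold change with BsAb, as estimate ± SE, of 8 genes called the same way in all 4 cell experiments, one colour per cell line. CCN1 lies between −0.74 and −3.59 and MYL9 between −0.32 and −2.58, while TXNIP, BHLHE40 and EGLN3 lie above 0 in each line.

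The treatment effect in DU-145 PTEN-mt cells was set against that in DU-145 cells. YAP/TAZ targets fell less, with a median difference of 0.97 and 15 of 20 genes called, 17 adjusted over the list alone (camera adjusted p = 2.98e-26, adjusted p = 7.5e-05 with an estimated correlation). ANKRD1 had a log2 fold change of −1.98 in PTEN-mt and −5.05 in DU-145 cells (difference 2.996, adjusted p = 6.13e-05), and CCN1 differed by 2.39. IGFBP3 rose in one and fell in the other (1.89 and −1.33, difference 3.15), and S100A9 rose by 3.50 against 0.13 (difference 3.30, SE 0.29, adjusted p = 5.1e-06). S-phase genes fell less as well, with a median difference of 0.75 and 20 of 21 called, 21 adjusted over the list alone (camera adjusted p = 6.53e-27, adjusted p = 0.0201 with an estimated correlation). ERK output genes differed by a median of 0.73 (11 of 20 called, 11 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.73e-11, adjusted p = 0.0016 with an estimated correlation). Interferon-stimulated genes had a median difference of −0.07 (camera adjusted p = 0.253). ITGB3 differed by 1.36 (adjusted p = 9.41e-05), and ITGA5 had a difference of 0.54 (adjusted p = 0.26). ITGB5 differed by 0.31 (adjusted p = 0.0143), uncalled without PTEN-mt control 2 (0.29) or BsAb 2 (0.285), or DU-145 control 2 (0.259) or BsAb 2 (0.297). In all, edgeR found 1945 genes with a more positive log2 fold change in PTEN-mt than in DU-145 cells, which includes weaker falls, and 1065 with a more negative one, and library size alone turned this split to 1074 and 2214. The counts were 1370 and 590 without PTEN-mt control 2 and 1386 and 603 without PTEN-mt BsAb 2. Without DU-145 control 1, control 2, BsAb 1 and BsAb 2 they were 1430 and 639, 1403 and 603, 1434 and 584, and 1413 and 643.

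PC-3 cells were set against DU-145 cells in the same way, over 24 libraries with limma. FOSL1 had a log2 fold change of 0.04 in PC-3 and −3.20 in DU-145 cells (difference 3.26, SE 0.19, adjusted p = 8.79e-09), and DKK1 −0.47 and −3.73 (difference 3.28). ACTA2 moved the other way (−3.32 and 0.31, difference −3.62), though RNA of other human cells may be part of its fall in PC-3. YAP/TAZ targets differed by a median of 1.31 with 14 of 20 called, 15 adjusted over the list alone (camera adjusted p = 1.63e-08, adjusted p = 0.00283 with an estimated correlation), and ERK output genes by 1.08 with 13 higher and 2 lower of 20 in both counts, the one adjusted over the list alone included (camera adjusted p = 9.99e-07, adjusted p = 0.00283 with an estimated correlation). Interferon-stimulated genes differed by −1.64, with 18 of 22 called and 22 adjusted over the list alone (camera adjusted p = 9.33e-12, adjusted p = 0.161 with an estimated correlation). In all, 2560 genes had a more positive and 1270 a more negative log2 fold change in PC-3 cells, a split that library size alone turned to 1084 and 2917. The counts were 2077 and 832 without DU-145 BsAb 1, and 2067 and 1740 by edgeR on recovered reads. ITGA5 had a difference of 0.21 (adjusted p = 0.839).

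C4-2B cells were set against the mean of DU-145 and PC-3 cells, as the series title concerns basal-type cancers. CXCL8, outside C4-2B's named rises, had 2.77 there, −1.13 in DU-145 and −0.11 in PC-3 cells (difference 3.32, SE 0.52, adjusted p = 0.000508). YAP/TAZ targets differed by a median of 0.89 with 13 of 20 called, 15 adjusted over the list alone (camera adjusted p = 2.52e-08, adjusted p = 0.00314 with an estimated correlation). Mitochondrially encoded genes differed by −0.58 with 6 of 13 called, 13 adjusted over the list alone (camera adjusted p = 2.52e-08, adjusted p = 0.25 with an estimated correlation). Of all genes, 1490 had a more positive and 444 a more negative log2 fold change in C4-2B cells, against 790 and 633 with library size alone and 938 and 660 by edgeR on recovered reads. The counts were 840 and 214 without C4-2B control 1 and 976 and 255 without control 2. They were 876 and 220 without BsAb 1, and 910 and 293 without BsAb 2. Simulated at under 2-fold, this contrast brought 36 false calls beside 37 true ones.

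The xenografts were set against the cells. For the libraries labelled DU-145 xenograft, which carried the expression of PC-3, the comparison with DU-145 cells spans 2 lines. CCN1 had −0.39 in them and −3.59 in DU-145 cells (difference 3.18, SE 0.11, adjusted p = 1.76e-09), and ITGB3 differed by 1.40 (adjusted p = 0.000282). ITGA5 differed by −1.21 (adjusted p = 0.0116) and ITGAV by −0.67 (0.00415), but by −0.462 and −0.373 without xenograft control 1, still called, and the ITGA5 difference was uncalled over the 8 libraries of the contrast alone (−1.267, adjusted p = 0.0786). There, 2546 genes had a more positive and 1885 a more negative log2 fold change than in DU-145 cells, a split that library size alone turned to 1361 and 3631. Against PC-3 cells, a comparison added after the values were seen and tested with limma over 24 libraries, the counts were 88 and 76. For PC-3, TAGLN had −0.27 in the xenograft and −3.04 in cells (difference 2.76, SE 0.34, adjusted p = 0.000969), and the myosin kinase gene MYLK 0.83 and −1.11 (difference 1.94, adjusted p = 0.00296). Mitochondrially encoded genes had a median difference of −0.56, with 1 of 13 called and 9 adjusted over the list alone (camera adjusted p = 4.25e-10, adjusted p = 0.427 with an estimated correlation). With limma 52 genes had a more positive and 19 a more negative log2 fold change in the xenograft, 71 in all, against 0 from the 8 libraries of the contrast alone (1198 at an unadjusted p under 0.05) and 26 by edgeR on recovered reads. The counts were 14 and 2 without PC-3 cell control 1, 23 and 5 without control 2, 36 and 1 without BsAb 1, and 39 and 12 without BsAb 2. They were 569 and 264 without xenograft control 1, 106 and 35 without xenograft control 2, and 60 and 38 without xenograft BsAb 2.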

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

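The differences in the counts and named genes below follow a rule set before the data were examined. Chosen after the results were seen were the differences of the libraries labelled DU-145 xenograft from both PC-3 sets and the tests of their identity. So were the tests of the falls in PC-3 cells, and of silent genes and the largest genes in DU-145 cells. The test for library size in DU-145 cells was written before its result.

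Each result here differed in its treatment effect between 2 groups, by a test of the difference itself. A positive difference means a more positive log2 fold change in the group named first, so a weaker fall counts as positive. The counts of genes with a positive and a negative difference were 1945 and 1065 for DU-145 PTEN-mt minus DU-145 cells, 2560 and 1270 for PC-3 minus DU-145 cells, and 1490 and 444 for C4-2B cells minus the mean of DU-145 and PC-3 cells. They were 2546 and 1885 for the libraries labelled DU-145 xenograft minus DU-145 cells, and 52 and 19 for PC-3 xenograft minus PC-3 cells. Library size alone turned this split to 1074 and 2214, 1084 and 2917, and 1361 and 3631 for the differences of DU-145 PTEN-mt cells, PC-3 cells and the libraries labelled DU-145 xenograft from DU-145 cells. These splits therefore depend on the scaling. On simulated data, false calls numbered 3, 6, 36, 78 and 61 for these differences in turn. Differences resting on falls in PC-3 cells, as for ACTA2 and CAVIN1 (0.877 and 0.0882 CPM in PC-3 xenografts), share the limit of those falls given below. Several genes named below were not tested in 1 or more of the groups compared, which gave no fold change of their own. These are EGLN2 and CAMKV (DU-145 cells), ADAMTS6 and BCL2A1 (PC-3 cells), G0S2, SEMA3D and FLG (C4-2B cells), ADGRF1 (C4-2B and DU-145 cells), NAPSA (C4-2B and PC-3 cells), HOXB6, CNTN1 and SV2A (the libraries labelled DU-145 xenograft), and MRPS24 and TAX1BP3 (PC-3 cells, against the xenograft).

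For DU-145 PTEN-mt minus DU-145 cells, the 5 largest positive differences were in NOG (3.334), S100A9 (3.297), SLCO2A1 (3.203), IGFBP3 (3.15) and ANKRD1 (2.996), and the 5 largest negative ones in EGLN2 (−4.477), ATOH8 (−2.792), CCDC122 (−1.869), ATRIP (−1.764) and MATN2 (−1.704). The calls ended, without the DU-145 library given, for the difference for NOG, DU-145 PTEN-mt cells minus DU-145 cells (control 1, 3.222, and BsAb 1, 2.427), the difference for EGLN2, DU-145 PTEN-mt cells minus DU-145 cells (control 1, −4.452, control 2, −4.460, and BsAb 2, −3.771) and the difference for ATRIP, DU-145 PTEN-mt cells minus DU-145 cells (control 2, −1.218).

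For PC-3 minus DU-145 cells they were NOG (3.321), ADAMTS6 (3.317), WNT7A (3.304), DKK1 (3.284) and FOSL1 (3.26), against SDK1 (−3.727), FEZ1 (−3.721), REEP2 (−3.684), ACTA2 (−3.624) and SV2A (−3.546). The call ended for the difference for SV2A, PC-3 cells minus DU-145 cells, when any of the 8 libraries of these 2 lines was left out (−3.404 to −3.688).

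For C4-2B cells minus the mean of DU-145 and PC-3 cells they were G0S2 (3.742), CXCL8 (3.319), BCL2A1 (3.24), CAVIN1 (2.769) and EFEMP1 (2.694), against ADGRF1 (−2.441), NAPSA (−2.344), SEMA3D (−2.328), FLG (−2.208) and ADAMTS15 (−2.065). Without the C4-2B library given, calls ended for BCL2A1 (control 2, 2.7), EFEMP1 (control 1, 2.4, BsAb 1, 2.8, and BsAb 2, 2.5), ADGRF1 (control 1, −2.4, control 2, −2.5, and BsAb 1, −1.5) and NAPSA (control 2, −1.8, and BsAb 1, −1.9). With edgeR on recovered reads calls ended for ADGRF1, NAPSA, SEMA3D and FLG.

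For the libraries labelled DU-145 xenograft minus DU-145 cells they were NOG (4.746), DKK1 (3.664), BDNF (3.245), CCN1 (3.181) and EFEMP1 (2.972), against HOXB6 (−5.256), CNTN1 (−4.648), EGLN2 (−4.568), SV2A (−4.22) and CAMKV (−4.1). The difference for HOXB6, DU-145 xenograft minus DU-145 cells, turned to 1.629 without xenograft control 1. Calls ended for the difference for CNTN1, DU-145 xenograft minus DU-145 cells, without xenograft control 2 (−1.898) or BsAb 2 (−3.444), and for the difference for SV2A, DU-145 xenograft minus DU-145 cells, without xenograft control 2 (−0.576). They ended without DU-145 control 1, control 2 or BsAb 2 for the difference for EGLN2, DU-145 xenograft minus DU-145 cells (−4.544, −4.552 and −3.862) and the difference for CAMKV, DU-145 xenograft minus DU-145 cells (−4.076, −4.084 and −3.639).

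For PC-3 xenograft minus PC-3 cells they were ACTA2 (3.744), TAGLN (2.764), MRPS24 (2.504), SERPINE1 (2.46) and MYLK (1.942), against TAX1BP3 (−1.582), MT-ATP8 (−1.059), FMNL1 (−1.058), ZNF875 (−0.779) and H6PD (−0.646). None of the 10 kept its call in all alternatives, as the 8 libraries of the contrast alone gave 0 genes with limma (1198 at an unadjusted p under 0.05) and ended the calls of TAGLN and MYLK as well, which no single library left out did. Calls ended, without the library given, for the difference for ACTA2, PC-3 xenograft minus PC-3 cells (xenograft BsAb 1, 3.669, and BsAb 2, 3.818, and cell control 1, 3.717, control 2, 3.771, BsAb 1, 3.866, and BsAb 2, 3.621), for the difference for MRPS24, PC-3 xenograft minus PC-3 cells (xenograft BsAb 2, 2.370, and cell control 2, 2.188, BsAb 1, 2.504, and BsAb 2, 2.504) and for the difference for SERPINE1, PC-3 xenograft minus PC-3 cells (cell control 1, 2.415). They also ended for the difference for TAX1BP3, PC-3 xenograft minus PC-3 cells (cell control 1, −1.355, and BsAb 2, −1.448) and for the difference for MT-ATP8, PC-3 xenograft minus PC-3 cells (xenograft BsAb 1, −1.006, and BsAb 2, −1.112, and cell control 1, −0.904, control 2, −1.214, and BsAb 1, −0.904). The same held for the difference for FMNL1, PC-3 xenograft minus PC-3 cells (xenograft BsAb 1, −1.092, and BsAb 2, −1.026, and cell control 2, −0.819, BsAb 1, −1.163, and BsAb 2, −0.954). So it did for the difference for ZNF875, PC-3 xenograft minus PC-3 cells (xenograft BsAb 1, −0.733, and cell control 1, −0.728, control 2, −0.831, and BsAb 1, −0.690) and for the difference for H6PD, PC-3 xenograft minus PC-3 cells (xenograft BsAb 1, −0.602, and cell control 1, −0.578, control 2, −0.715, BsAb 1, −0.623, and BsAb 2, −0.670).

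The libraries labelled DU-145 xenograft had Spearman correlations of 0.925 to 0.936 with PC-3 cells and 0.79 to 0.807 with DU-145 cells, so tumours grown from PC-3 cells are a candidate explanation of the differences from DU-145 cells. Their treatment effect differed from that of PC-3 cells in 88 genes upward and 76 downward (2185 at an unadjusted p under 0.05, limma over 24 libraries), from that of the PC-3 xenograft in 433 and 836 (3526 unadjusted) by the same test, and from that of DU-145 cells in 2546 and 1885 by edgeR over 16 libraries, so part of the gap to the last counts can lie in the tests. Genes of DU-145 kept 0.308% of their level in DU-145 cells, which argues against a mixture in which DU-145 cells are the larger part. Genes of PC-3 kept 46% of theirs in PC-3 xenografts, and the ratio of these shares, 0.00671, argues against a change of DU-145 cells in the host. A small share of DU-145 cells, and at which step a label was exchanged, stay open.

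Of the genes at least 2-fold lower with BsAb in PC-3 cells, 78.4% lay under 0.5 CPM in PC-3 xenografts, against 14.3% of genes matched by level, so RNA of other human cells in the control libraries may explain part of the falls. A single source at 1 share per library would lower genes silent in PC-3 alike, and their fold changes spread by 2.2 times their own SE (1.7 times the median SE), as for GFAP (−3.12, SE 0.15) and CTNNA1 (−1.19, SE 0.15), which argues against it, while several sources, or some expression in cultured cells, stay open. KLK3, at 0 CPM in PC-3 xenografts, was higher with BsAb in PC-3 cells (log2 0.48, adjusted p = 0.0984), against the direction of the falls, and was not called. A response of PC-3 cells stays open for the 26 genes with at least 1 CPM in PC-3 xenografts, among them SERPINE1 (−2.65), THBS1 (−1.87) and CRYAB (−2.10). The response and a different admixture cannot be told apart in these 26, as a gene read in PC-3 xenografts can also be read in other cells.

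Weakly expressed genes, under 2 CPM, were higher with BsAb in DU-145 cells with a median of 0.404. Thinning to 1 library size gave a median of 0.402, which decides nothing, as fold changes are scaled for size. Reads over 308 olfactory receptor genes rose, from 38 and 40 in the controls to 78 and 92 with BsAb, but the gain per gene, 0.0042 CPM, was 0.0156 of the 0.269 CPM gained by the weakly expressed genes. This argues against a background of reads over silent genes as the main source, and the share of the 100 largest genes differed by −0.436 percentage points, which argues against a few genes taking the counts. GC content, gene length and RNA input were not tested, so these, library size and an antibody effect stay open.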

How the results depend on the processing

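Alternatives chosen after seeing the data are named above. A DESeq2 size factor alternative was not run for the PC-3 tables, whose values are already scaled by medians of ratios. For called genes named, 547 of 558 checks gave the same call in DU-145 cells, 456 of 515 in PC-3, 482 of 490 in DU-145 PTEN-mt and 393 of 426 in C4-2B cells. Uncalled genes were called in 120 of 382 checks in the libraries labelled DU-145 xenograft and 54 of 463 in the PC-3 xenograft. For lists, 91 of 98, 102 of 119, 77 of 84, 76 of 84, 68 of 84 and 80 of 96 checks gave the same call in DU-145, PC-3, DU-145 PTEN-mt and C4-2B cells, the libraries labelled DU-145 xenograft and the PC-3 xenograft. For differences of genes, 124 of 130 (DU-145 PTEN-mt minus DU-145), 131 of 140 (PC-3 minus DU-145), 167 of 180 (C4-2B minus the mean), and 83 of 140 (PC-3 xenograft minus PC-3) did, and for the DU-145 xenograft label minus DU-145, 13 of 130 ended a call and 1 turned the sign. Library size alone gave 7035 higher and 3080 lower genes in DU-145 cells and 107 and 487 in PC-3 cells. DESeq2 gave 2905 and 4345 in DU-145 cells, 131 and 144 in PC-3 cells, 764 and 599 in C4-2B cells, 220 and 169 in the libraries labelled DU-145 xenograft, and 21 and 16 in the PC-3 xenograft. Sharing the spread over 12 groups gave 3551 and 2965 in DU-145 cells, which turned the split of 4493 and 4897, 7 and 112 in PC-3, 1706 and 1863 in DU-145 PTEN-mt, 16 and 31 in C4-2B cells, 831 and 1056 in the libraries labelled DU-145 xenograft and 173 and 144 in the PC-3 xenograft. No filter gave 751 and 652 in the libraries labelled DU-145 xenograft, and genes of the PC-3 xenograft 221 and 168 in PC-3 cells. At least 2-fold, by construction fewer, genes changed in DU-145 cells numbered 1824, genes changed in PC-3 cells 182, genes changed in DU-145 PTEN-mt cells 726, and in C4-2B cells 81. Shared genes at 2-fold, higher and lower, were 1 and 9 (DU-145, PC-3), 198 and 40 (DU-145, PTEN-mt), 1 and 3 (DU-145, C4-2B), 0 and 5 (PC-3, PTEN-mt), 0 and 2 (PC-3, C4-2B), and 5 and 1 (PTEN-mt, C4-2B). With an estimated correlation 0 lists passed in any of the 6 experiments, and with fry 23 in DU-145 cells, 2 in PC-3 cells, 19 in DU-145 PTEN-mt cells, 13 in C4-2B cells, and 0 in each xenograft set. Leaving out 1 library gave 174 to 221 higher and 158 to 338 lower in PC-3, 2324 to 2900 and 2343 to 2879 in DU-145 PTEN-mt, 270 to 1411 and 259 to 1188 in C4-2B, 0 to 1819 and 0 to 1971 in the libraries labelled DU-145 xenograft and 0 to 198 and 0 to 163 in the PC-3 xenograft. The libraries of the contrast alone, and leaving out 1 library, gave 5276 and 1960 to 2358 genes whose treatment effect differs, DU-145 PTEN-mt cells minus DU-145 cells, and 6092 and 2909 to 3221 genes whose treatment effect differs, PC-3 cells minus DU-145 cells. They gave 2809 and 3365 to 6116 genes whose treatment effect differs, DU-145 xenograft minus DU-145 cells, 0 and 16 to 833 genes whose treatment effect differs, PC-3 xenograft minus PC-3 cells, and 4240 and 1054 to 1707 for C4-2B cells minus the mean. For PC-3 xenograft minus PC-3, the replicate block gave 25 and edgeR on recovered reads 26. The cause was not tested for these. Signs turned for the list of hypoxia and glycolysis genes in DU-145 xenograft without control 1 (0.145, against −0.832 without control 2), ITGA5 in PC-3 xenograft without control 2 (0.865, against −1.038 without control 1), the list of S-phase genes in PC-3 xenograft without control 2 (−0.072, against 0.403 without control 1), and the difference for HOXB6, DU-145 xenograft minus DU-145 cells, without xenograft control 1 (1.629, against −7.422 without xenograft BsAb 1). Deviations of libraries with the same replicate number correlated by −0.169 in DU-145, 0.03 in PC-3, −0.058 in DU-145 PTEN-mt and −0.028 in C4-2B cells, −0.065 in the libraries labelled DU-145 xenograft and −0.272 in the PC-3 xenograft. A replicate block gave 4359 and 4783, 238 and 371, 3200 and 3140, 1194 and 1097, 0 and 0, and 0 and 0 higher and lower genes in that order. The crossed pairing gave 4774 and 5114 in DU-145 cells and 70 and 43 in the PC-3 xenograft. Replicate spread limits the xenografts, where few simulated 1.5-fold changes were recovered.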

Other observations

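Lists that passed camera and were not described above follow. In DU-145 cells, hypoxia and glycolysis genes fell, 14 lower and 2 higher of 19 (median −0.53, camera adjusted p = 6.66e-07, adjusted p = 0.125 with an estimated correlation), with SLC2A1 at −1.30, HK2 at −1.65 and PGK1 at −0.75. FOXO targets rose, 11 with 3 lower of 15 (median 0.76, camera adjusted p = 1.42e-05, adjusted p = 0.138 with an estimated correlation), with the pro-apoptotic gene BCL2L11 at 1.66 and SESN3 at 1.40. Histone genes rose, 10 of 12 (camera adjusted p = 0.000267, adjusted p = 0.292 with an estimated correlation), as did lysosome and autophagy genes, 12 with 3 lower of 21 (0.0055, 0.245). Basal epithelial markers fell, 8 with 1 higher of 11 (0.0128, 0.596), and focal adhesion components, 12 with 3 higher of 18 (0.021, 0.596), while luminal prostate markers went 5 up and 5 down of 11 (0.0173, 0.596). In DU-145 PTEN-mt cells, epithelial junction genes (8 higher and 4 lower of 15, 0.000187, 0.187), squamous differentiation genes (4 higher of 8, 1.12e-05, 0.187) and fatty acid synthesis genes (6 higher of 9, 0.000279, 0.187) rose, with CLDN4 at 1.60, CDH3 at 1.17, CDH1 at 0.99 and FADS2 at 0.56. Actin and SRF targets fell there, 9 with 1 higher of 16 (2.85e-05, 0.187), FOXO targets rose, 9 with 2 lower of 15 (0.0136, 0.247), and ERK output genes fell, 11 with 4 higher of 20 (0.0211, 0.35). The pairs in brackets give the camera adjusted p and that with an estimated correlation.

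In C4-2B cells, ATF4 targets (5 higher of 20, 1.53e-05, 0.134), heat-shock genes (7 higher of 12, 1.53e-05, 0.134), p53 targets (6 higher and 1 lower of 22, 3.99e-05, 0.134) and cholesterol biosynthesis genes (9 higher and 1 lower of 20, 0.00098, 0.18) passed camera upward, with INSIG1 at 0.44 and SLC7A11 at 0.32. Lysosome and autophagy genes passed downward (6 lower of 25, 0.00098, 0.36). Interferon-stimulated genes had 6 higher and 1 lower of 25 (median 0.23, 0.0461, 0.764), with OAS2 at 1.12. ERK output genes (5 higher of 17, 0.0022, 0.272), basal epithelial markers (4 higher of 18, 0.046, 0.604) and ER unfolded-protein response genes (4 higher and 1 lower of 16, 0.046, 0.377) passed upward, and YAP/TAZ targets (2 lower and 1 higher of 18, 0.00473, 0.274) and extracellular matrix and integrin ligands (4 lower and 3 higher of 26, 0.00611, 0.36) downward. In PC-3 cells, histone genes (3 higher of 15, 0.00243, 0.363), luminal prostate markers (4 higher of 17, 0.00928, 0.363), ERK output genes (2 higher of 20, 0.00705, 0.363), basal epithelial markers (2 higher of 17, 0.0146, 0.363) and FOXO targets (2 higher and 1 lower of 15, 0.0238, 0.363) passed upward, and focal adhesion components (2 lower of 18, 0.00279, 0.363), fibroblast and pericyte markers (2 lower and 1 higher of 7, 0.0197, 0.363) and TGF-beta targets (3 lower and 1 higher of 18, 0.0477, 0.466) passed downward. Heat-shock genes passed downward with 1 of 10 lower (0.00138, 0.379), and the call ended for the list of heat-shock genes in PC-3 cells without BsAb 1 (−0.083).

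In the libraries labelled DU-145 xenograft, where 0 genes were called by edgeR against 2303 at an unadjusted p under 0.05, further lists passed downward. They were cholesterol biosynthesis genes (median −0.32, 0.00142, 0.608), actin and SRF targets (−0.28, 0.0129, 0.486), YAP/TAZ targets (−0.19, 0.0062, 0.486), heat-shock genes (−0.12, 0.0118, 0.486), neuroendocrine markers (−1.48, 0.0143, 0.486), NF-kB and inflammatory genes (−0.34, 0.0409, 0.486) and mesenchymal genes (−0.21, 0.0453, 0.541), and mitochondrially encoded genes passed upward (0.14, 0.0143, 0.543). The call of the list of cholesterol biosynthesis genes in DU-145 xenograft libraries ended without control 1 (−0.066). Lists that passed in no experiment were, with the smallest camera adjusted p of each, integrin subunits of αv and α5β1 (0.108), other integrin subunits (0.25), androgen-response genes (0.193), cell death regulators (0.344), endothelial markers (0.128), leukocyte markers (0.298) and muscle and adipose markers (0.835).

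The following tests were written before their results, save those of pooled interferon-stimulated genes and their splits. NRF2 targets, without the genes already seen, may widen the rise of AKR1C1 and GPX2. They rose in DU-145 cells, 13 with 4 lower of 20 (camera adjusted p = 0.000224, adjusted p = 0.35 with an estimated correlation), and in DU-145 PTEN-mt cells, 16 with 1 lower of 20 (6.26e-22, 0.176). In PC-3 cells the list had an adjusted p of 0.895 and in the PC-3 xenograft 0.724, and it was lower in C4-2B cells, 5 of 20 (0.0201, 0.508), and in the libraries labelled DU-145 xenograft, with 0 of 20 called by edgeR (0.000529, 0.486). Antigen presentation genes rose in DU-145 PTEN-mt cells, 13 with 1 lower of 15 (3.41e-08, 0.176), with adjusted p of 0.962 in C4-2B cells (0.964 with an estimated correlation), 0.0786 in the libraries labelled DU-145 xenograft (0.593) and 0.0184 in the PC-3 xenograft (0.89), where 0 of 14 genes were called by limma. In DU-145 and PC-3 cells 4 of its genes could be read, too few for a list test. All 4 rose in DU-145 cells, PSMB10 by 1.23, NLRC5 from 9.84 to 20.7 CPM, ERAP1 by 0.44 and ERAP2 by 0.45 on the log2 scale, and none was called in PC-3 cells, where the smallest adjusted p was that of ERAP2, 0.714. A list of neural and glial markers for the falls in PC-3 cells was dropped, since 4 of its genes could be tested.

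Over 24 libraries, the treatment effects of the 2 xenograft sets differed in 433 genes upward and 836 downward in the libraries labelled DU-145 xenograft. This was not tested on their 8 libraries alone, and cell libraries, whose replicates differed less, shared the spread. As both tables carry the expression of PC-3, the 8 libraries were fitted together. Over 15541 genes limma called 0, with 945 under an unadjusted p of 0.05 and a smallest adjusted p of 0.151. As no split can give fewer, that 34 of 34 splits gave as many (65 at most) says nothing about chance. Interferon-stimulated genes, looked at after that count of 0, were higher as a group (median 0.817, camera adjusted p = 3.04e-24, adjusted p = 0.398 with an estimated correlation), with 15 of 22 genes passing over the list alone. For their median, 3 of 34 splits were as far from 0, with 0.999 as the highest of the others, so chance is not excluded. BST2 had 2.04 and IFI6 2.3, both with an adjusted p of 0.151.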
